A study of Homo sapiens with 4 samples.

How the data were processed

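RNA of SH-SY5Y cells, a human neuroblastoma line, was measured on 4 Agilent 2-colour arrays. Each array paired the Cy5-labelled cRNA of cells treated for 6 h with CAPE or DBL with the Cy3-labelled cRNA of cells given medium only, per the labels' protocols, from 200 ng of total RNA and 4 days after plating. CAPE replicate 1 and DBL replicate 1 shared the control sample of set 1, and CAPE replicate 2 and DBL replicate 2 that of set 2, per the labels. No dyes were swapped, so an effect of the dye on a gene cannot be separated from treatment against control; it cancels in CAPE minus DBL. All 4 arrays lay on one slide, so no slide or scan batch could be tested. Doses are not given in the sources used here.

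The scanner output holds spot intensities per channel on a linear scale, a background intensity, and a log10 ratio of Cy5 over Cy3, all made with Agilent Feature Extraction per the file headers. The headers name version 11.0.1.1 and the submitters' processing notes version 10.7.3.1. The authors' deposited value table holds log2 ratios. Set against the scanner output, each of its columns equalled the log2 of Cy5 over Cy3 processed signal of 1 array to within 2.86e-06, so its scale, direction and lack of further centring are known. Its column medians were 0.04 for CAPE 1, 0.02 for DBL 1, 0.03 for CAPE 2 and 0.04 for DBL 2. The columns of DBL 1 and CAPE 2 equalled each other's scanner values. The table's CAPE columns thus hold the arrays of set 1, and its DBL columns those of set 2. The scanner values, with the sample each belongs to, were used throughout, and the table as an alternative.

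Median spot signals and median background signals were used, where the design fixed in advance had named mean spot signals. Background was corrected with limma's normexp and an offset of 50, which pulls the ratios of dim probes towards 0. Ratios were normalised within each array by loess with control spots at weight 0. Control spots and spots with an outlier flag were then left out, spots of a probe were averaged, and a probe was kept where at least 2 of the 8 channel measurements were well above background. Of 34127 probes, 25771 (75.5%) took a gene symbol by matching the design's accession, without version, to a table of human RefSeq genes (assembly GRCh38.p14); the others kept the design's name. No coordinates are printed, because the array's design names an older build. A probe not well above background on any array of a group has only a bound, written as at least a fold. It sets the other channel against, per array, the higher of the lowest signal well above background and the probe's own, after loess and Aquantile scaling, and is open to dye bias. The brightest kept probe stood for a gene, which left 21328 genes or transcripts, 15910 of them with a symbol.

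The array number limits the precision. Each array had 43118 spots other than controls. Between 75.5% and 78.5% of these were well above background in Cy3, and between 71.1% and 75.1% in Cy5. Between 0.786% and 0.928% of spots had an outlier flag and 0 were saturated. The labels speak of 2 sets of samples and do not say more about how the cultures were kept apart, so the p-values measure the spread between these samples, which may be partly technical.

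Log2 ratios were fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3) with a mean for each compound over all 4 arrays. The mean of each compound was tested against 0, and CAPE minus DBL as a contrast, with Benjamini-Hochberg adjustment and a threshold of 0.05. Values are given as mean ± SD of 2 arrays. Each set had 1 control sample, so the control's own spread enters the test only through the difference between the sets. In simulated data with 21328 genes, of which 100 were changed by a log2 ratio of 0.5 with CAPE, 100% were recovered with 14 false calls, and CAPE minus DBL recovered 93% of them with 2 false calls. All 100 genes changed by a log2 ratio of 1 were recovered in these fits. The noise was normal with each gene's fitted spread, and a small list of genes was changed besides these 200. Where fewer genes differ the adjustment is stricter, so these rates do not say which differences CAPE minus DBL could miss in the arrays themselves.

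The sets pair the samples, because the labels say that the number marks a shared control. The check was the correlation across genes of the set difference of CAPE with that of DBL, which was 0.39; the control channels of one set correlated at 0.999 and 0.998, against 0.992 to 0.993 between sets. A fit with the set as a replicate block is given where it changes a call. In the simulated data this block gave 162 false calls for CAPE against control and 24 for CAPE minus DBL. The block leaves the set differences out of the error of a compound's mean; the cause of the false calls in CAPE minus DBL was not tested.

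Before the data were examined, 18 gene lists were fixed, covering stress responses, metabolism, cell cycle, neuronal identity and the substrate-adherent cell type found in this line. Their 425 members include 409 that were kept, 9 list symbols being updated through unique synonyms. Members not measured or not kept, such as AKR1C2, CA9 and NFE2L2, are not analysed here. A list was tested with limma's camera and a preset inter-gene correlation of 0.01, adjusted over the 18 lists. Camera with an estimated correlation was the alternative, and fry is given beside it. The correlation was estimated from only the few residual degrees of freedom of 4 arrays. Genes were named by a rule fixed at the same time. For each compound these were the 12 highest and 8 lowest symbols past the threshold with one sign in both arrays, up to 4 members per list with the smallest p, and 14 fixed stress and dopamine genes. For CAPE minus DBL they were the 5 largest differences if fewer than 5 passed. Not every gene this rule takes is reported here. Probes of near-identical genes (HSPA1A and HSPA1B, the MT1 genes, the AKR1C genes, histones and ribosomal proteins) may not tell the copies apart, so their values are uncertain for a single copy.

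Other background corrections, scalings, filters, probe rules, tests and subsets of the arrays were run as alternatives, as was the value table with its 2 columns exchanged. Simulations of compounds with no effect were drawn 100 times. To mimic the shared controls, they took the correlation of the set differences observed in the data.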

Results

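The series concerns the protection of SH-SY5Y neuroblastoma cells against 6-hydroxydopamine, a dopamine analogue toxic to catecholaminergic neurons, by caffeic acid phenethyl ester (CAPE) and dihydroxybenzalacetone (DBL). Both molecules carry a catechol ring joined to an α,β-unsaturated carbonyl group, which is a phenethyl ester in CAPE and a methyl ketone in DBL. No toxin was present in the samples measured here. Transcript levels were compared between cells treated for 6 h with either compound and cells given medium only, on 2 arrays per compound. Each set of samples had 1 control, shared by the CAPE and the DBL array of that set. Log2 ratios are those of treated cells over control, and the limma test across all 21328 genes is meant by each adjusted p.

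CAPE raised genes of the antioxidant response and of protein folding in the endoplasmic reticulum (ER). HMOX1, which encodes the haem-degrading enzyme heme oxygenase 1, had the highest log2 ratio, 3.91 ± 1.12 (SD, n = 2, 15.0-fold, adjusted p = 0.000458). SLC7A11, the cystine transporter subunit that supplies glutathione synthesis, rose by a log2 ratio of 1.88 ± 0.0059 (3.69-fold), and HSPA5, the major ER chaperone, by 1.88 ± 0.20. The next highest were DNAJC3 (1.79 ± 0.16), CRELD2 (1.63 ± 0.08), HSP90B1 (1.54 ± 0.11), MANF (1.53 ± 0.04), P4HA2 (1.52 ± 0.69), PDIA4 (1.49 ± 0.20), DNAJB11 (1.43 ± 0.13), CALR (1.41 ± 0.02) and CREB3L2 (1.40 ± 0.08), nearly all of them chaperones or enzymes of the ER. Among the lowest were RD3 (-1.69 ± 0.28, 3.23-fold lower), FAM30A (-1.26 ± 0.75), the cytokine gene LTB (-1.24 ± 0.28), PAX7 (-1.12 ± 0.12), UBD (-1.08 ± 0.45), TNFAIP2 (-1.07 ± 0.50) and the helicase gene PIF1 (-1.04 ± 0.33).

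**Figure D1:**
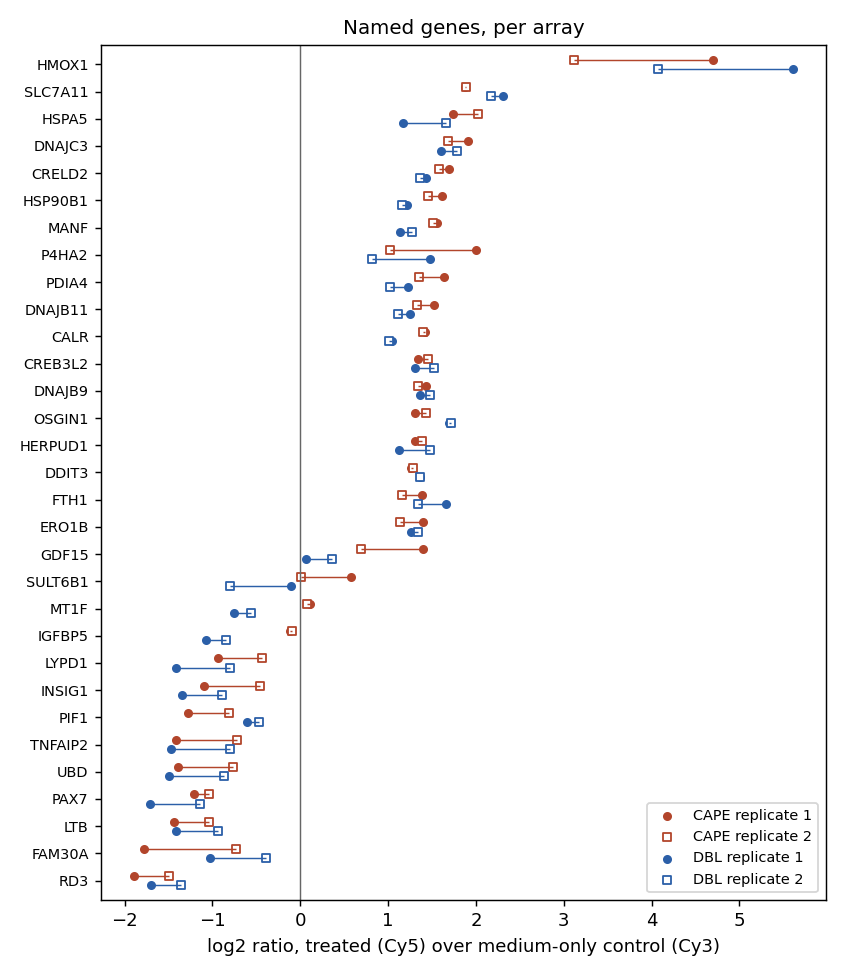
Log2 ratio of treated over medium-only control (horizontal axis) for most of the highest and lowest named genes and the largest differences between the compounds, with 1 point per array and a line joining the 2 arrays of a compound. HMOX1 lies from 3.12 to 4.70 with CAPE and from 4.07 to 5.61 with DBL, above all the other genes drawn.

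With CAPE, 5643 genes passed the threshold, 3135 higher and 2508 lower, and 92.5% of them differed from control by less than 1.5-fold. By size alone, 34 genes were over 2-fold higher in both CAPE arrays and 3 were over 2-fold lower in both. The higher and lower counts were 114 and 70 with the scanner software's log ratio and 60 and 12 with an offset of 0. They were 125 and 2 with median centring, 153 and 158 with the deposited value table, and 72 and 29 in CAPE replicate 1 alone. The count past the threshold was 2073 with a normexp offset of 0, 1142 with the scanner software's log ratio, 441 when tested against a minimum change of 1.2-fold, and 1939 without CAPE replicate 1. It was 13269 with median centring in place of loess, which moved the median of all genes to 0.11 and the share of higher calls from 55.6% to 66.7%.

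The list of ER chaperones and ER-associated degradation genes had 25 of 27 measured members higher and 0 lower with CAPE, with a median log2 ratio of 0.98 (camera adjusted p = 2.34e-23, and adjusted p = 0.297 with an estimated correlation). Of the NRF2 antioxidant targets, 23 of 32 rose (median 0.39, adjusted p = 5.27e-11, and adjusted p = 0.549 with an estimated correlation). Besides HMOX1 and SLC7A11 these included the growth inhibitor OSGIN1 (1.37 ± 0.09), the ferritin heavy chain FTH1 (1.27 ± 0.16), the sulfiredoxin SRXN1 (0.88), the quinone reductase NQO1 (0.77 ± 0.33) and TXNRD1 (0.49 ± 0.08). GCLM, a subunit of the enzyme that begins glutathione synthesis, had a log2 ratio of 0.01 ± 0.05 (adjusted p = 0.92), and of 0.29 with median centring (adjusted p = 0.00368). Among the ATF4 and CHOP targets, 17 of 33 rose (median 0.30, adjusted p = 6.91e-08, and adjusted p = 0.549 with an estimated correlation). DDIT3, which encodes CHOP, rose by 1.28 ± 0.02, the transporter chain SLC3A2 to 0.92, TRIB3 by 0.45 ± 0.10, SESN2 by 0.37 ± 0.06 and ATF4 itself by 0.23 ± 0.05, while ATF3 was at 0.01 ± 0.23 (adjusted p = 0.95). SLC7A11 stands in both of these lists.

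Of the hypoxia list, 16 of 24 members rose with CAPE and 0 fell (median 0.64, adjusted p = 3.49e-08, and adjusted p = 0.574 with an estimated correlation). Its named members were the collagen hydroxylase P4HA2, the transferrin receptor TFRC (0.94), ANKRD37 (0.72), NDRG1 (0.68) and INSIG2 (0.68). The median of this list was 0.89 in set 1 and 0.35 in set 2. That of the cholesterol list below was -0.58 and -0.24, and that of the NF-kB targets -0.34 and -0.15. For the other lists that passed, the sets were within 2 times. Of the autophagy and lysosome genes, 15 of 35 rose (median 0.15, adjusted p = 0.00031, and adjusted p = 0.549 with an estimated correlation), led by WIPI1 (1.31), GABARAPL1 (1.11) and the cargo receptor SQSTM1 (0.75 ± 0.10). The heat shock list had 9 of 24 higher and 2 lower (median 0.10, adjusted p = 0.0141, and adjusted p = 0.574 with an estimated correlation), with DNAJB4 at 0.95, the collagen chaperone SERPINH1 at 0.83 and HSPA1A at 0.59 ± 0.07. That call ended without CAPE replicate 2 (adjusted p = 0.0944), with the scanner software's log ratio (0.0955), with the mean of a gene's probes (0.0737) and with the deposited value table (0.117, or 0.0999 with its 2 columns exchanged).

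All 21 measured mitosis genes fell with CAPE (median -0.57, adjusted p = 7.65e-16, and adjusted p = 0.549 with an estimated correlation). Examples were the kinesin KIF20A (-0.86), the checkpoint kinase gene BUB1B (-0.83), the centromeric histone CENPA (-0.78) and TOP2A (-0.75). Of the genes of cholesterol synthesis and uptake, 15 of 21 fell and 1 rose (median -0.39, adjusted p = 4.21e-06, and adjusted p = 0.574 with an estimated correlation), among them the synthase gene HMGCS1 (-0.88), the SREBP-retaining INSIG1 (-0.78 ± 0.45) and MVK (-0.69). Of the NF-kB targets, 10 of 19 fell and 0 rose (median -0.23, adjusted p = 2.60e-05, and adjusted p = 0.574 with an estimated correlation), with the chemokine gene CCL2 at -0.86 and RELB at -0.47. CXCL2 was well above background in only 1 of its 2 treated spots, so the size of its fall with CAPE is uncertain. Its fitted log2 ratio was -0.60, and it was -1.08 with an offset of 0 and -1.85 with the scanner software's log ratio. Adjusted over the list alone, the counts with CAPE were 25 of the ER list, 23 of the NRF2 list with 1 lower, 18 of the ATF4 list, 18 of the hypoxia list, 16 of the autophagy list, 9 of the heat shock list with 2 lower, 21 mitosis genes lower, 15 cholesterol genes lower with 2 higher, and 12 NF-kB targets lower.

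The remaining 9 lists did not pass with CAPE. Their camera adjusted p was 0.348 for metallothioneins, 0.506 for immediate early genes, 0.122 for p53 targets, 0.0857 for DNA replication, 0.506 for catecholaminergic neuron and neuroblastoma identity, 0.973 for substrate-adherent cell markers, 0.973 for the proteasome, 0.973 for aryl hydrocarbon receptor targets and 0.0857 for common reference genes. Members higher and lower with CAPE numbered 1 and 0 of 13 metallothionein genes, 4 and 7 of 24 immediate early genes, 7 and 3 of 20 p53 targets, 1 and 8 of 21 replication genes, 2 and 6 of 24 neuronal identity genes, 1 and 2 of 21 substrate-adherent markers, 5 and 5 of 32 proteasome genes, 2 and 2 of 7 receptor targets, and 6 and 2 of 15 reference genes. Adjusted over the list alone, these were 9 and 7 immediate early genes, 9 and 3 p53 targets, 3 and 7 neuronal identity genes, 6 and 5 proteasome genes and 7 and 2 reference genes, with the other 4 lists at the counts just given. With the replicate block, members higher numbered 4 for metallothioneins, 8 for immediate early genes, 2 for replication, 5 for neuronal identity, 5 for substrate-adherent markers and 9 for the proteasome. The p53 list passed without CAPE replicate 2 (adjusted p = 0.0121), and the replication and reference lists passed without CAPE replicate 1 (0.0495 and 0.0366). The replication list also passed with the mean of a gene's probes (0.0444). With median centring the p53 (0.0183), proteasome (0.000136) and reference (0.00118) lists passed. The growth-cone gene GAP43 (-0.55) and the receptor gene RET (-0.64) fell, as did CYP1B1 (-0.70), while TH, the rate-limiting enzyme of dopamine synthesis, was at -0.18 ± 0.09 (adjusted p = 0.0588, and 0.0173 with the replicate block). Of the common reference genes, RPL13A (0.89), RPLP0 (0.69) and EEF1A1 (0.56) were higher and TUBB (-0.46) was lower relative to the median of all genes. For the neuronal identity list, the substrate-adherent list and the proteasome, the median and the mean of the members differed in sign. Fry gave 3 lists past the threshold, the ER list (adjusted p = 0.0102), NRF2 targets (0.0499) and the common reference genes (0.0499), which camera did not call. None of the other lists called by camera with CAPE passed with fry.

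Several calls of single genes with CAPE ended with another processing. With the scanner software's log ratio, HMOX1 (adjusted p = 0.051), NQO1 (0.0902), TXNRD1 (0.0614), TRIB3 (0.0965), ATF4 (0.141), P4HA2 (0.0645), INSIG2 (0.0606) and NDRG1 (0.057) did not pass. Nor did HMGCS1 (0.0756), INSIG1 (0.0906), MVK (0.0567), CCL2 (0.0817), CXCL2 (0.0831), RELB (0.0539), TNFAIP2 (0.0796), UBD (0.0554), GAP43 (0.0525), EEF1A1 (0.0815), RPLP0 (0.0525) and TUBB (0.0554). The deposited value table with its 2 columns exchanged ended the calls of these genes and of PAX7 (0.0504) and WIPI1 (0.0501), and as deposited it ended those of ATF4, TRIB3, EEF1A1 and PIF1. With an offset of 0, NQO1 (0.071), TRIB3 (0.0617), ATF4 (0.119), HMGCS1 (0.0533), INSIG1 (0.0681), CCL2 (0.0647), CXCL2 (0.0629) and TNFAIP2 (0.0561) did not pass. Against a minimum change of 1.2-fold, NQO1, TXNRD1, TRIB3, SESN2, ATF4, INSIG1, INSIG2, CCL2, CXCL2, RELB, GAP43 and TUBB did not pass. ATF4 did not pass without CAPE replicate 1 (0.0944) or without CAPE replicate 2 (0.155), nor CXCL2 without CAPE replicate 1 (0.0595), EEF1A1 with the mean of its probes (0.198) or TUBB with median centring (0.20). ATF3 passed with median centring (0.02), and TH with no background correction (0.0318), with the filter on all channels (0.0483) and with the table as deposited (0.0217). The dim genes LTB and FAM30A passed with the scanner software's log ratio and had larger ratios there.

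DBL raised many of the same genes, with HMOX1 again the highest at 4.84 ± 1.08 (n = 2, 28.6-fold, adjusted p = 0.000172). SLC7A11 rose by 2.24 ± 0.10 (4.72-fold), OSGIN1 by 1.71 ± 0.01, DNAJC3 by 1.69 ± 0.12, FTH1 by 2.82-fold (SD 0.22 on the log2 scale), DNAJB9 by 1.42 ± 0.08, CREB3L2 by 1.41 ± 0.15 and HSPA5 by 1.41 ± 0.35. CRELD2 (1.40 ± 0.05), DDIT3 (1.36 ± 0.01), HERPUD1 (1.30 ± 0.25) and ERO1B (1.30 ± 0.06) followed. Among the lowest were RD3 (-1.53 ± 0.25, 2.88-fold lower), PAX7 (-1.43 ± 0.40), UBD (-1.18 ± 0.44), LTB (-1.17 ± 0.33), TNFAIP2 (-1.14 ± 0.47), INSIG1 (-1.12 ± 0.32) and LYPD1 (-1.11 ± 0.44).

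With DBL, 6024 genes passed, 3189 higher and 2835 lower, and 92.8% of them differed from control by less than 1.5-fold. There were 33 genes over 2-fold higher in both DBL arrays and 4 over 2-fold lower. These counts were 108 and 108 with the scanner software's log ratio and 55 and 15 with an offset of 0. They were 134 and 5 with median centring, 105 and 52 with the deposited value table, and 53 and 37 in DBL replicate 1 alone. The count past the threshold was 3012 with a normexp offset of 0, 2592 with the scanner software's log ratio, 507 against a minimum change of 1.2-fold, and 2489 without DBL replicate 1. With median centring it was 13478, and the share of higher calls moved from 52.9% to 67.6%.

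The ER list had 24 of 27 members higher with DBL (median 0.93, adjusted p = 7.21e-21, and adjusted p = 0.332 with an estimated correlation). Of the NRF2 targets, 24 of 32 rose (median 0.52, adjusted p = 6.33e-15, and adjusted p = 0.417 with an estimated correlation), among them SRXN1 (1.17), SQSTM1 (1.03 ± 0.21, also in the autophagy list), NQO1 (0.96 ± 0.41) and TXNRD1 (0.79 ± 0.20). GCLM was at 0.05 ± 0.09 (adjusted p = 0.59), and at 0.36 with median centring (adjusted p = 0.00105). Of the ATF4 and CHOP targets 15 of 33 rose (median 0.20, adjusted p = 7.50e-05), of the heat shock list 13 of 24 with 2 lower (median 0.21, adjusted p = 0.000179), of the autophagy list 16 of 35 with 1 lower (4 lower with the replicate block, median 0.15, adjusted p = 0.00035), and of the hypoxia list 11 of 24 (18 with the replicate block, median 0.46, adjusted p = 9.95e-06). Each of these 4 had an adjusted p = 0.538 with an estimated correlation. Of the lists that passed with DBL, the medians of set 1 and set 2 differed by 2 times or more for ATF4 and CHOP targets (0.07 and 0.24), autophagy (0.25 and 0.10), hypoxia (0.62 and 0.27) and metallothioneins (-0.29 and -0.14). ATF3 (0.43 ± 0.09), ATF4 (0.32 ± 0.12), TRIB3 (0.48 ± 0.24), SESN2 (0.26 ± 0.02) and HSPA1A (0.80 ± 0.07) passed.

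With DBL, 16 of 21 genes of the cholesterol list fell and 2 rose (median -0.49, adjusted p = 7.32e-08), including HMGCS1 (-1.04) and MVK (-0.88). Of the mitosis genes, 16 of 21 fell (median -0.29, adjusted p = 7.66e-08), with BUB1B at -0.58 and KIF20A at -0.57. Of the NF-kB targets, 8 of 19 fell (median -0.14, adjusted p = 0.000229), with CCL2 at -0.82, TNF at -0.65 and CXCL2 at least 1.57-fold lower because it was not well above background in the treated channel. Each of these 3 lists had an adjusted p = 0.538 with an estimated correlation. The metallothionein list had 7 of 13 members lower and 2 higher (median -0.22, adjusted p = 0.0487, and adjusted p = 0.669 with an estimated correlation), with MT1F at -0.66 ± 0.13, MT1X at -0.42 and MT1E at -0.41. The metallothionein call ended without DBL replicate 1 (adjusted p = 0.132), with no background correction (0.0544), with an offset of 0 (0.129), with the scanner software's log ratio (0.0931), with the deposited value table (0.656, or 0.091 with its 2 columns exchanged) and with median centring (0.212), and the mitosis call ended with median centring (0.219).

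The other 8 lists did not pass with DBL, with a camera adjusted p of 0.212 for immediate early genes, 0.957 for p53 targets, 0.11 for DNA replication, 0.138 for neuronal identity, 0.364 for substrate-adherent markers, 0.287 for the proteasome, 0.858 for aryl hydrocarbon receptor targets and 0.099 for common reference genes. In the same order, members higher and lower with DBL numbered 10 and 4 of 24, 4 and 3 of 20, 1 and 6 of 21, 3 and 7 of 24, 1 and 4 of 21, 12 and 4 of 32, 2 and 2 of 7, and 5 and 3 of 15. Adjusted over the list alone, these were 5 and 3 p53 targets, 4 and 8 replication genes, 3 and 9 neuronal identity genes, 14 and 6 proteasome genes, 4 and 2 receptor targets and 6 and 3 reference genes, with the immediate early and substrate-adherent lists at the counts just given. With the replicate block, 7 immediate early genes and 5 p53 targets were lower, 5 replication genes were higher and 10 lower, and 4 receptor targets and 8 reference genes were higher. Without DBL replicate 1 the replication (adjusted p = 0.0432) and neuronal identity (0.0275) lists passed, with the deposited value table the replication list did (0.0272), and with median centring the replication (0.0254), proteasome (1.27e-05) and reference (0.000958) lists passed. For the p53 and the substrate-adherent list, the median and the mean differed in sign. CYP1B1 (-1.04) and GAP43 (-0.90) fell, TH was at -0.22 ± 0.06 (adjusted p = 0.026), and the early genes DUSP5 (0.49) and EGR1 (0.36) rose. Adjusted over the list alone, the counts with DBL were 25 of the ER list, 25 of the NRF2 list, 15 of the ATF4 list, 13 of the heat shock list with 2 lower, 18 of the autophagy list with 3 lower, 14 of the hypoxia list, 16 cholesterol genes lower with 2 higher, 17 mitosis genes lower, 9 NF-kB targets lower and 8 metallothionein genes lower with 2 higher. Fry gave 4 lists past the threshold, the ER list (adjusted p = 0.0136), NRF2 targets (0.0301), heat shock (0.0426) and the common reference genes (0.0426), which camera did not call. None of the other lists called by camera with DBL passed with fry.

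Single calls with DBL depended on the processing in the same way. ATF3 (adjusted p = 0.0537), ATF4 (0.0699), TRIB3 (0.0658), NQO1 (0.0568), HMGCS1 (0.0525), INSIG1 (0.052), CCL2 (0.0781), CXCL2 (0.059), TNFAIP2 (0.0633), LYPD1 (0.0503), MT1E (0.0576), MT1X (0.0649) and TH (0.118) did not pass with the scanner software's log ratio, nor with the exchanged columns of the value table. With an offset of 0, ATF3 (0.0569), ATF4 (0.0584), CCL2 (0.0637), MT1E (0.0528) and TH (0.07) did not pass, and with median centring MT1E (0.101), MT1X (0.114) and TH (0.639) did not. Against a minimum change of 1.2-fold, ATF3, ATF4, TRIB3, SESN2, CCL2, CXCL2, KIF20A, MT1E, MT1X, DUSP5, EGR1 and TH did not pass. The calls of SESN2 (0.0781), MT1E (0.0767) and TH (0.295) ended without DBL replicate 1, those of ATF4 (0.11), SESN2 (0.0861) and TH (0.0606) without DBL replicate 2, and that of ATF3 with the mean of its probes (0.0809). The table as deposited, whose DBL 1 column holds the values of CAPE 2, ended those of ATF3, ATF4, TRIB3, SESN2, NQO1, TXNRD1, INSIG1, CCL2, CXCL2, TNF, BUB1B, KIF20A, MT1E, MT1F, MT1X, CYP1B1, GAP43, DUSP5, EGR1, LYPD1, PAX7 and TH. ERO1B, LTB, UBD and TNF passed with the scanner software's log ratio and had larger ratios there.

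**Figure D2:**
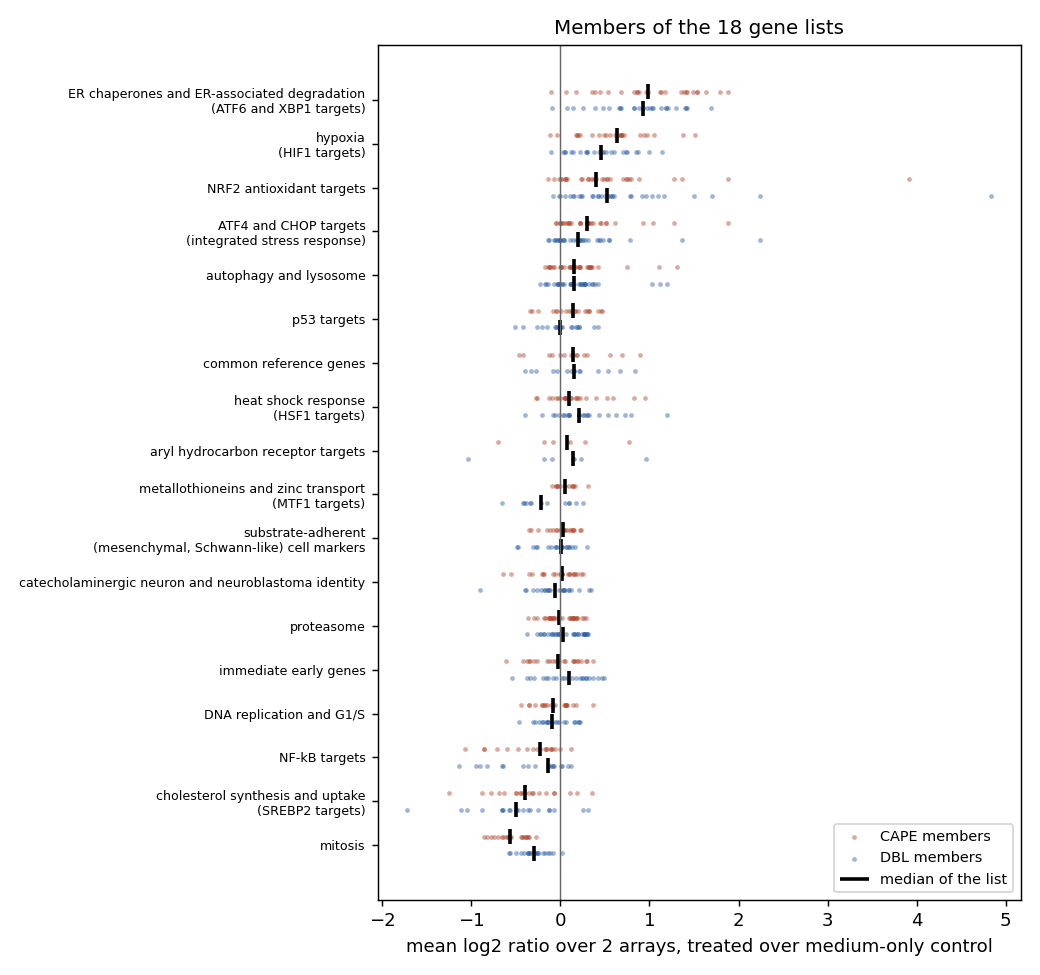
Mean log2 ratio over 2 arrays (horizontal axis) of each measured member of the 18 gene lists, with CAPE above DBL in each row and a black bar at the median. The ER list has the highest medians (0.98 and 0.93) and the mitosis list the lowest with CAPE (-0.57).

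CAPE and DBL were then compared with each other at the same 6 h; how their doses compare is not given in the sources used here. The log2 ratios of the compounds correlated across genes with a Pearson r of 0.866 and a Spearman rho of 0.801, genes not being independent replicates. Simulated compounds with no effect gave an r of 0.389, but their correlation was set to the 0.39 observed between the set differences. That r returns its setting and is no separate yardstick. The covariance was 0.0407 against a simulated 0.00164, which rests on the same setting and on the fitted spread. The arrays of different compounds and sets, which share no control sample, correlated at 0.737 and 0.771. Of the genes past the threshold, 2253 were higher with both compounds, against 469 for independent lists, and 1795 were lower with both, against 333. Opposite calls were made for 4 genes, against 792. The simulated compounds shared at most 1 call, but they had at most 4 calls with CAPE, so that overlap sets no scale for these counts. Part of the excess may come from the shared controls, and all 4 arrays share the dye orientation. Of the genes over 2-fold higher in both arrays, 26 were shared by the compounds, including HMOX1, SLC7A11, HSPA5, DDIT3, OSGIN1 and FTH1.

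**Figure D3:**
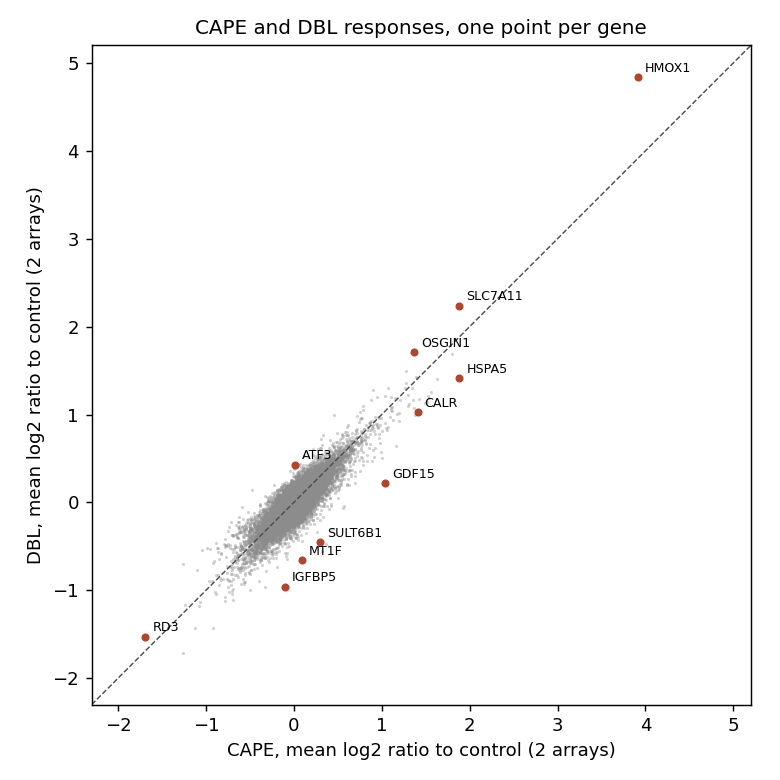
Mean log2 ratio to control with CAPE (horizontal axis) and DBL (vertical axis), 1 grey point per gene, with named genes in red and a dashed line of equal ratios. The points follow the line (r = 0.866), with HMOX1 above it and HSPA5, GDF15, MT1F and IGFBP5 below it.

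No single gene passed the test of CAPE minus DBL in limma (0 genes, with 1419 at an unadjusted p under 0.05). With the replicate block 5 passed (2754 unadjusted), namely HMOX1, IGFBP5, SULT6B1, MT1F and 1 transcript without a symbol, and with an intensity trend 3 passed. HMOX1 had the largest difference by symbol, -0.93, lower with CAPE (95% interval -2.16 to 0.30, adjusted p = 0.822), and with the block the interval was -1.08 to -0.78 (adjusted p = 0.0123). IGFBP5, an insulin-like growth factor binding protein, was at -0.10 ± 0.02 with CAPE and -0.96 ± 0.16 with DBL, a difference of 0.85 (interval 0.64 to 1.07, adjusted p = 0.219, and 0.0296 with the block). The stress cytokine gene GDF15 was at 1.04 ± 0.50 with CAPE and 0.22 ± 0.21 with DBL, a difference of 0.82 (interval 0.37 to 1.28, adjusted p = 0.658, and 0.172 with the block). MT1F differed by 0.75 (interval 0.55 to 0.95, adjusted p = 0.219, and 0.0415 with the block) and SULT6B1 by 0.74 (interval 0.22 to 1.27, adjusted p = 0.658, and 0.0299 with the block). SULT6B1 was at 0.29 with CAPE (adjusted p = 0.221, and 0.00227 with the block) and -0.45 with DBL (0.0717, and 0.00031 with the block). It passed with DBL with no background correction (-0.57, adjusted p = 0.0373), with median centring (-0.58, adjusted p = 0.00848) and with DBL arrays alone (0.00995). Leaving out a CAPE array repeats the DBL fit of the DBL arrays alone, so it is no further alternative. With CAPE it passed with CAPE arrays alone (0.0116), a fit that leaving out a DBL array repeats. GDF15 with DBL passed with median centring (0.47, adjusted p = 0.0147) and with DBL arrays alone (0.0358). Its CAPE call ended with the scanner software's log ratio (1.08, adjusted p = 0.0624), with the deposited value table (0.212) and with its 2 columns exchanged (0.0634). MT1F with CAPE passed with median centring (0.32, adjusted p = 0.00258), and the IGFBP5 call with DBL ended with the deposited value table (0.395). Without 1 array in turn the count ranged from 0 to 19, and it was 12 without DBL replicate 1, 19 without CAPE replicate 2 and 19 without DBL replicate 2. The lone array of a compound is then assumed to vary like the others. GDF15 passed without CAPE replicate 2 (adjusted p = 0.00648) and without DBL replicate 2 (0.00784), HMOX1 without DBL replicate 2 (0.00626), and SULT6B1 without DBL replicate 1 (0.000239). IGFBP5 and MT1F passed without DBL replicate 1 (0.00307 and 0.0147), without CAPE replicate 2 (0.0272 and 0.0324), without DBL replicate 2 (0.000144 and 0.00108) and with the intensity trend (0.0469 for both).

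CREB3L2, DNAJB9 and DDIT3 rose with both compounds, and the intervals of their differences included 0. The intervals given here come from the fit without the replicate block, so they do not use the pairing by set. Within the sets, DDIT3 was lower with CAPE each time (1.26 against 1.37, and 1.29 against 1.36). CREB3L2 and DNAJB9 differed in opposite directions in set 1 and set 2. CREB3L2 differed by -0.01 (interval -0.23 to 0.21), DNAJB9 by -0.03 (-0.22 to 0.16) and DDIT3 by -0.09 (-0.26 to 0.09). GCLM, which passed with neither compound, differed by -0.04 (-0.23 to 0.15). HSPA5 differed by 0.47 (0.11 to 0.83) and CALR by 0.38 (0.20 to 0.56), both higher with CAPE, and SLC7A11 by -0.36 (-0.55 to -0.17) and OSGIN1 by -0.34 (-0.53 to -0.15), both higher with DBL. These intervals are not adjusted for the number of genes, and none of these 8 genes passed, although HSPA5 did without DBL replicate 2 (adjusted p = 0.0154).

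As lists, 10 of 18 differed between the compounds, 5 higher and 5 lower with CAPE, and 0 did with an estimated correlation. Mitosis genes were lower with CAPE by a median of -0.27 (adjusted p = 6.62e-15, and adjusted p = 0.563 with an estimated correlation). NRF2 targets were lower with CAPE by -0.15 (adjusted p = 5.35e-08, and 0.504 estimated), immediate early genes by -0.11 (adjusted p = 2.76e-05, and 0.504 estimated), the heat shock list by -0.08 (adjusted p = 0.00144, and 0.563 estimated) and the proteasome by -0.05 (adjusted p = 0.0208, and 0.758 estimated). Metallothioneins were higher with CAPE by 0.32 (adjusted p = 8.89e-07, and 0.563 estimated), ER chaperones by 0.09 (adjusted p = 1.46e-05, and 0.504 estimated), p53 targets by 0.13 (adjusted p = 0.00221, and 0.563 estimated), the cholesterol list by 0.10 (adjusted p = 0.00259, and 0.758 estimated) and the hypoxia list by 0.13 (adjusted p = 0.0162, and 0.831 estimated). Between set 1 and set 2 these differences were within 2 times for NRF2 targets, metallothioneins and p53 targets only. In the others the medians were -0.40 and -0.13 for mitosis, -0.16 and -0.07 for immediate early genes, -0.14 and -0.05 for heat shock, -0.07 and -0.02 for the proteasome, 0.18 and 0.04 for ER chaperones, 0.07 and 0.16 for cholesterol, and 0.26 and 0.04 for hypoxia. The hypoxia call turned without CAPE replicate 1 (adjusted p = 0.000302) and ended without DBL replicate 2 (0.455), with an offset of 0 (0.0792) and with the scanner software's log ratio (0.0555). The p53 call ended without CAPE replicate 1 (0.375) and without DBL replicate 2 (0.0598), the cholesterol call without DBL replicate 1 (0.763) and without CAPE replicate 2 (0.574), the heat shock call without DBL replicate 1 (0.10), and the proteasome call without CAPE replicate 1 (0.225) and without DBL replicate 1 (0.312). With the deposited value table, CAPE minus DBL sets set 1 against set 2, because 2 columns hold each other's values. The compounds cancel in it, so its calls do not test the difference between them. In it the ER (0.831), heat shock (0.805), metallothionein (0.070), immediate early (0.134), mitosis (0.0699) and proteasome (0.928) calls ended. The NRF2 and cholesterol calls turned, and the autophagy list (0.0127) and NF-kB targets (1.42e-05) passed. ATF4 and CHOP targets missed the threshold (adjusted p = 0.0734) and passed with the block (0.0252), with the scanner software's log ratio (0.0306), without CAPE replicate 1 (0.0236) and without DBL replicate 2 (5.14e-05). The other 7 lists did not pass, with an adjusted p of 0.837 for autophagy, 0.845 for NF-kB targets, 0.814 for DNA replication, 0.49 for neuronal identity, 0.0734 for substrate-adherent markers, 0.848 for aryl hydrocarbon receptor targets and 0.915 for common reference genes. NF-kB targets passed without CAPE replicate 1 (0.00192), without DBL replicate 1 (0.0315) and without CAPE replicate 2 (0.00141), and substrate-adherent markers without CAPE replicate 1 (0.000302). For NF-kB targets and aryl hydrocarbon receptor targets, the median and the mean differed in sign. Adjusted over the list alone, 8 metallothionein genes, 3 ER genes, 1 ATF4 target and 1 receptor target were higher with CAPE than with DBL, and 2 NRF2 targets, 1 ATF4 target and 1 immediate early gene were lower, with 0 in the other 12 lists. Fry gave 0 lists.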

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

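The tests on the exchanged columns were chosen after the match had been seen. In the deposited value table, which the comparisons above do not use, the columns of DBL 1 and CAPE 2 correlated with the scanner values of their own samples at an r of only 0.688, and each equalled the other's scanner values to within 2.86e-06. The columns of CAPE 1 and DBL 2 equalled their own. If the scanner output had been given to the wrong samples, arrays labelled with one set would not share a control, but the control channels differed within a set by 0.417 times as much as between sets (SDs of 0.15 and 0.17 against 0.38 to 0.39), which argues against it. With the table's assignment the same ratio was 1.41, which is consistent with the 2 columns of the table having been exchanged. No biological explanation was tested.

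The files also report spike-in probes, which the comparisons do not use. Per the file headers, these had a Cy5 over Cy3 intercept, at an expected ratio of 1, of 1.84-fold in CAPE 1, 1.62-fold in DBL 1, 1.64-fold in CAPE 2 and 1.76-fold in DBL 2, with a mean of 1.71. The slope of observed on expected log ratios lay between 0.828 and 0.838.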

How the results depend on the processing

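The value table with exchanged columns, and the block with an estimated correlation, were chosen after seeing the data. Past the threshold with CAPE and DBL were 2073 and 3012 genes with a normexp offset of 0, 1142 and 2592 with the scanner software's log ratio, 13269 and 13478 with median centring, 441 and 507 against a minimum change of 1.2-fold, and 926 and 2528 with the value table's columns exchanged. The table as deposited gave 1234 for DBL. Genes over 2-fold higher in both arrays numbered 60 and 55 with an offset of 0, 114 and 108 with the scanner's log ratio and again with exchanged columns, 125 and 134 with median centring, and 153 and 105 with the table as deposited. Genes over 2-fold lower numbered 12 and 15, 70 and 108 (also with exchanged columns), 2 and 5, and 158 and 52 under these settings, 3 and 6 with no background correction, and 1 and 2 with the mean of a gene's probes, against 3 and 4 in the report. The correlation of the compounds was then 0.781, 0.779, 0.775, 0.930 and 0.757. CAPE minus DBL gave 5 genes with the replicate block and 3 with an intensity trend. Its lists past the threshold numbered 6 with the table as deposited, where it sets set 1 against set 2 and does not compare the compounds. All 3 comparisons had 0 lists past the threshold with an estimated correlation, and 0 with the replicate block and an estimated correlation. For CAPE and DBL the replicate block gave 8192 and 8560 genes. Of the genes printed here, it brought past the threshold TH with CAPE, SULT6B1 with each compound, and HMOX1, IGFBP5, MT1F and SULT6B1 in CAPE minus DBL; of the lists, ATF4 and CHOP targets in CAPE minus DBL (adjusted p = 0.0252). It ended the call of the ribosomal protein family in CAPE minus DBL (0.0572), and changed no other call of a list or family printed here or of a gene printed in the report.

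Without 1 array in turn, the genes past the threshold ranged from 1939 to 5952 for CAPE, 2489 to 7006 for DBL and 0 to 19 for CAPE minus DBL. Genes over 2-fold higher ranged from 34 to 72 and from 33 to 53, those over 2-fold lower from 3 to 29 and from 4 to 37, and the correlation from 0.801 to 0.850. Lists ranged from 9 to 11, 10 to 11 and 8 to 11. Leaving out an array leaves 1 array of its compound. Counts over 2-fold are then those of that single array, so they could only rise. For the other compound's ratio to control, the fit is that of its own arrays alone, which gave the upper ends of 5952 and 7006. The cause of the other changes was not tested. Quantile scaling of the mean intensities leaves ratios as they are and tests nothing. No filter on dim probes, a filter on all channels, no background correction and the mean of a gene's probes kept each of the 3 gene counts and both counts of genes over 2-fold higher within 1.5 times.

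With median centring the sign turned for EGR1 (0.21), MT1E (0.21), MT1H (0.21) and NFKB1 (0.027) with CAPE, and for GATA2 (0.11), KLF6 (0.20), PSMC3 (0.040), TP53I3 (0.063) and TUBB (0.048) with DBL. With the mean of a gene's probes it turned for PPIA (-0.073 with CAPE and -0.00011 with DBL), and with the table as deposited for CHGA with DBL (-0.042). The table as deposited also turned the NRF2 list (adjusted p = 0.00689) and the cholesterol list (adjusted p = 1.35e-08) of CAPE minus DBL, and leaving out CAPE replicate 1 turned its hypoxia list (adjusted p = 0.000302, in a range from 9.74e-18 to 0.455 without 1 array in turn). Over the named genes and all alternatives, 4009 values kept their call, 546 lost it, 106 gained one and 12 turned in sign. A turn was counted only where the main or the alternative fit gave a call, so turns without a call are among those kept. The kept values include those of the quantile scaling, which tests nothing. Signal over background limits the dim genes, whose ratios the offset of 50 pulls towards 0.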

Other observations

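Gene families other than the fixed lists were examined after those lists had been seen, so 14 families were defined by symbol alone and the members named here were chosen after their values were seen. Some members also stand in a fixed list, so these families are not separate evidence. Examples are RPL13A (reference genes), SEC61B and SEC24D (ER), HK2 and ALDOC (hypoxia) and KIF20A (mitosis). Ribosomal protein genes stood out, with 70 of 85 higher with CAPE (median log2 ratio 0.46, camera adjusted p = 6.32e-27, and adjusted p = 0.0633 with an estimated correlation) and 68 of 85 with DBL (median 0.41, adjusted p = 1.36e-22, and 0.0748 estimated); RPS2 was at 1.11 and 1.07. Of these genes 3 were lower with CAPE and 5 with DBL, and the family was higher with CAPE than with DBL by 0.04 (adjusted p = 0.0387, 0.0572 with the replicate block and 0.674 estimated). Replication-dependent histone genes went down, with 55 of 62 lower with CAPE (median -0.48, adjusted p = 5.68e-28, and 0.448 estimated) and 37 lower and 1 higher with DBL (median -0.23, adjusted p = 1.74e-12, and 0.62 estimated), a median that turned to 0.05 for DBL with median centring. The histone list was also lower with CAPE than with DBL by -0.25 (adjusted p = 4.69e-29, and 0.674 estimated).

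Further steps of the secretory pathway shifted with the ER chaperones. Of the ER translocon genes 13 of 20 rose with CAPE and 14 with DBL, led by TRAM1 (1.19 and 1.02), and 1 (SRP9) fell with each, with an estimated-correlation adjusted p of 0.179 for both compounds. Of the oligosaccharyltransferase subunits 8 of 11 and 7 of 11 rose, led by MAGT1 (1.35 and 1.16; 0.215 and 0.284 estimated), and 1 (OST4) fell with DBL. Of the COPII coat and ER exit genes 9 of 14 and 10 of 14 rose, led by KDELR2 (0.76 and 0.72; 0.179 estimated for both), and 1 (SEC13) fell with each. In all, 8 of 14 families passed with CAPE and 9 with DBL at the preset correlation, and 0 with the estimated one. The others that passed were glycolysis enzymes (higher), complex I and ATP synthase subunits (lower, and higher with median centring) and, with DBL, HOX genes (lower). Families of tRNA synthetases, kinesins, collagens, fatty acid synthesis and potassium channels did not pass.

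The 2 medium-only controls differed from each other, and this difference is part of the means and SDs of the ratios to control above. Each was hybridised on 2 arrays, so these are values of 1 sample against 1. In the control channel, set 1 minus set 2, the median of the substrate-adherent cell markers was -0.68 on the log2 scale, below all 10000 random lists matched on brightness, and that of the neuronal identity list was 0.37, above all of them. The NRF2 list was at -0.27, also below all random lists, with 30 of 32 members lower in set 1. HMOX1 was at -2.10 and NQO1 at -0.99, while GCLM was at -0.02. The mitosis and cholesterol lists were at 0.22 and 0.23, each above all random lists. The NF-kB list was at 0.21 over all arrays, also above all of them, with 13 of 19 members higher in set 1. It was at 0.14 on the CAPE arrays and 0.12 on the DBL arrays. Metallothioneins (percentile 99.9), DNA replication (99.89), ATF4 and CHOP targets (99.36) and autophagy (0.5) also lay near the ends of the random lists. Random lists drew genes singly, while genes of a fixed list are not independent. A place beyond them is therefore no measure of significance. In the treated channels HMOX1 differed between the sets by -0.54, so its ratios of 4.70 and 5.61 in set 1 and 3.12 and 4.07 in set 2 differ mostly through the control.

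Of the tests on the larger ratios of set 1, those for the hypoxia and the cholesterol list apart were chosen after the result was seen. Members of these lists past the threshold with both compounds shifted more in set 1 than in set 2, in 26 of 27 genes (median size 0.79 against 0.45), as did 16 of 16 mitosis genes, 19 of 22 NRF2 targets and, less strongly, 3136 of all 4048 shared calls (ratio of medians 1.27 against 1.76 for the 27 genes), but only 4 of 14 ATF4 and CHOP targets (0.859). A compression of all ratios in set 2 as the whole cause is argued against, because ER chaperone genes were larger in set 1 in only 12 of 24 and the ER chaperone genes' ratio of set 1 over set 2 was 0.515 times that of these genes (95% bootstrap interval 0.411 to 0.677). For both lists together, 32.2% of the median set difference lay in the control channel, with a bootstrap interval too wide to decide (-3.46 to 88.7). For mitosis genes and NRF2 targets the median control-channel part (0.22 and 0.39) exceeded the median set difference (0.15 and 0.12). Their treated channels went the other way (-0.08 and -0.24). For the hypoxia genes the share of the mean set difference was -10.6% (interval -32.0 to 9.06), which argues against the control channel as its place on these arrays. For the cholesterol genes it was 79.8% (52.7 to 105), so a higher control level in set 1 may account for that part and stays open. All these bootstrap intervals resample genes of a list, which are not independent. With 1 control sample per set, they do not measure the spread between samples. A difference between the treated cultures in oxygen supply or density is a hypothesis that was not tested.

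Of the tests on the many small shared changes, the one between sets and the one on ribosomal proteins were chosen after the result was seen. With both compounds in one direction, 3770 genes passed by under 1.5-fold and 278 by 1.5-fold or more. A dye effect of single probes as the whole cause is argued against by second probes with another sequence. They had the same sign in 84.6% of the 914 smaller changes with one (95% interval 82.1 to 86.9) and in 93.7% of 63 larger ones. Their medians in the first probes' direction were 0.15 against 0.31 for the smaller changes and 0.43 against 0.76 for the larger. A part of the size that belongs to single probes therefore stays open. The share with the same sign was 52.9% for 257 genes with an unadjusted limma p over 0.5 with both compounds. These were chosen for ratios near 0, so little agreement could be found whatever the cause, and they add no support. Over all genes, the shared controls as the whole cause are argued against by the r of 0.737 between arrays that share none. That r includes the larger changes, so the smaller ones were not tested apart, and a dye effect common to all arrays could also raise it. For the ribosomal protein genes 88.2% of 34 second probes agreed in sign (interval 72.5 to 96.7), with a median of 0.31 against 0.49 for the first probes. The interval reached below the bound set for a verdict against a dye effect of single probes. The test therefore left that effect undecided for the ribosomal protein genes. A dye effect common to all probes of a transcript stays open for every gene, since no array had the dyes swapped.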
